A study of Thalassiosira oceanica CCMP1005 with 9 samples.

How the data were processed

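RNA was extracted from cells collected on filters and treated with DNase, and strand-specific libraries (TruSeq Stranded mRNA) were made from the messenger fraction of 250 ng RNA, per the labels' protocols. Cultures were kept at 20 °C under continuous light of 200 µmol photons per square metre per second, per the labels' protocols. Sequencing was on an Illumina HiSeq instrument, per the series' design text. The submitters' processing notes name Trimmomatic 0.32, Bowtie and RSEM, with no role or order. Aligner settings, the assembly or genome build, the annotation and the strand setting of the counting are not given in the sources used here.

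Both tables deposited by the authors hold one column per sample and 25279 genes, and no replicates were pooled. The first holds estimated counts per gene, which the authors deposited as raw counts: between 16.3% and 24.5% of the values in a library are not whole numbers, as happens when reads that match several genes are divided among them. Genes that share sequence can therefore exchange reads, and their counts are uncertain to that extent. The second holds FPKM values that the authors deposited as normalized. In 5627 genes with a mean FPKM of at least 20, every value (100%) lay within 1% of the value obtained by dividing the count by 1 length per gene and by the library total scaled with TMM factors, so the FPKM table carries the same measurements as the counts after a TMM-like scaling. Lengths implied by that relation had a median of 1358 nt and quartiles of 689 and 2322 nt. Gene IDs have the form of a component number followed by a gene number within it; how components were defined is not given in the sources used here, and the files do not pair IDs with names. The gene lists and protein motif lists fixed in advance therefore could not be matched, and neither the set tests nor their alternatives were run.

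Groups and replicate numbers were taken from the sample titles. The comparisons, their tests, the rule for genes to name and most alternatives were fixed before the data were examined. Counts were rounded and genes with low counts removed with filterByExpr, which kept 16869 genes and 99.9% of all counts. Libraries were scaled by TMM (factors 0.931 to 1.07), and all 9 were fitted together with edgeR's robust quasi-likelihood model (edgeR 4.0.16 in R 4.3.3), so that the groups share one estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the quasi-likelihood F. Levels are CPM on TMM-scaled totals. Correlations and principal components used log2 CPM with a prior count of 2. With 3 libraries against 3, an exact permutation test of a single gene cannot give a p below 0.1, so p-values rest on the model's shared spread.

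Genes were named by rule: in each comparison the 2 that rose and the 2 that fell most among those past adjusted p 0.05, with a mean log2 CPM of at least 3 over the 9 libraries and no overlap between the libraries of the groups compared. The mean was taken over the log2 values, a reading settled after the files were seen. Taking the log2 of the mean CPM would have let in genes close to 0 in the Cu-limited libraries, such as c3684_g1. Classes of response over time, and the sets of genes at least 10-fold apart from both other groups, were defined after the data were seen.

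Library totals ranged from 12936675 to 28067858 counts, a 2.17-fold range. On counts simulated from the real means and library sizes with 200 changed genes, the same steps recovered 37.3%, 59.7% and 90.6% of genes changed 1.5-fold, 2-fold and 4-fold between Cu-limited and Cu-replete groups. For Cu-transient against Cu-replete groups they recovered 43.9%, 75.4% and 95.2%, and for Cu-limited against Cu-transient groups 40.6%, 65.7% and 93.7%. Between 7 and 15 unchanged genes were called per comparison. Changes of 1.5-fold were thus often missed in these simulations, and a gene that did not pass is not shown to be unchanged. The simulations changed only 200 genes and gave all groups the same spread, whereas 8.23% to 23.1% of tested genes passed in the data. Recovery and false calls may therefore differ in the data.

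Alternatives were other scalings (DESeq2's size factors, library totals alone), other filters on low counts, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom and limma on log2 FPKM (limma 3.58.1) with pseudocounts of 1 and 0.1, a fit of only the 6 libraries compared, a threshold of 0.01 and a test against a 2-fold change. Cyclic loess scaling, thinning of all libraries to the smallest total and the bands of gene abundance were added after the data were seen. The overlap of calls against the shared controls was set beside 20 simulations of 9 unchanged libraries drawn from the gene means and dispersions.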

Results

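Gene expression was measured by sequencing messenger RNA from Thalassiosira oceanica CCMP1005, a diatom of the open ocean, grown alone at 3 levels of copper supply. Copper is a cofactor of proteins that carry electrons in photosynthesis and respiration, and its supply limits the growth of this diatom in the low-copper medium. The Cu-replete cultures, named as the control, grew at their maximum rate in a synthetic seawater (Aquil medium) with 21.4 nM copper. The Cu-limited cultures grew in the same medium with 1 nM copper, at about 50% of the maximum rate. Both lines had been kept in their medium for more than 500 generations. The Cu-transient cultures were started by moving 2 ml of Cu-replete cells into 26 ml of copper-free medium, which left 1.4 nM copper. They were harvested about 4 generations later, when their maximum electron transport rate (a fluorescence measure of photosynthesis) had fallen midway between those of the adapted lines. Each group had 3 libraries. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

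The total count was 16296102, 14102290 and 21405784 in the Cu-replete libraries, 28067858, 13667919 and 17182399 in the Cu-limited libraries, and 13147433, 17229340 and 12936675 in the Cu-transient libraries. Of 25279 genes in the tables, 16869 had enough counts to be tested. The files do not pair gene IDs with names, and no genome was used here, so genes are described by ID, level and class of response, without position or function.

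The Cu-limited libraries stood apart from all others. Across genes, the correlation of log2 CPM (counts scaled by the library total) between libraries of one group was 0.977 to 0.989 in Cu-replete, 0.990 to 0.994 in Cu-limited and 0.989 to 0.990 in Cu-transient cultures. Between groups it was 0.975 to 0.987 for Cu-replete with Cu-transient, 0.971 to 0.977 for Cu-limited with Cu-transient, and 0.964 to 0.975 for Cu-limited with Cu-replete. The first principal component held 41.2% of the variance and placed the Cu-limited libraries at 41.98 to 47.6 and the other 6 at -27.1 to -16.5. The second held 24.3% and ran mainly along the Cu-replete libraries, from -53.8 in replicate 3 to 18.1 in replicate 1. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom was at least 5.03 within groups, and the highest within-group value, 29.2, was that of Cu-replete replicates 1 and 3. Genes differed among the 3 groups in 5057 cases, 30.0% of those tested, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05.

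**Figure D1:**
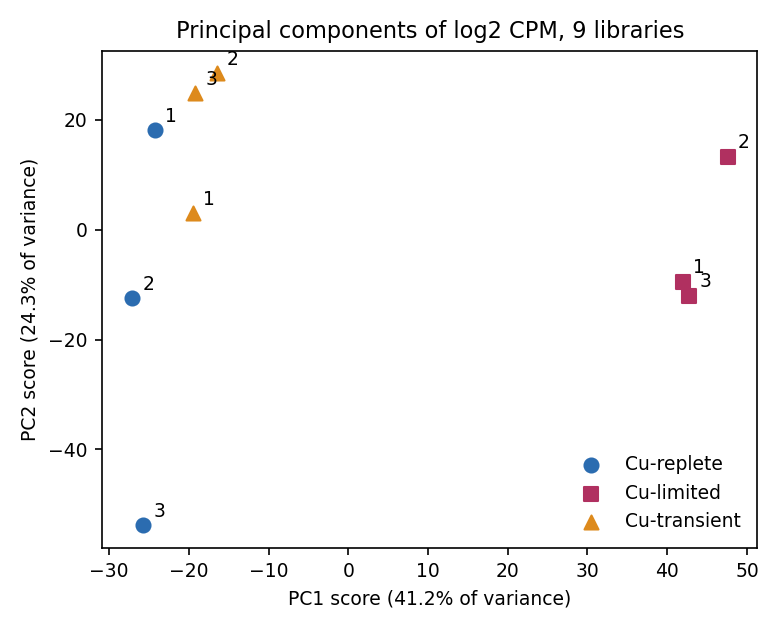
Scores of the 9 libraries on the first and second principal components of log2 CPM, with the replicate number beside each point. The Cu-limited libraries lie at 41.98 to 47.6 on the first component, and the Cu-replete and Cu-transient libraries lie at -27.1 to -16.5.

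The first comparison asked how cells adapted to low copper differ from cells adapted to ample copper. Expression of 3751 genes differed, 22.2% of those tested, with 1927 higher and 1824 lower in Cu-limited cells. Which direction had more calls depended on the setting: 1748 were higher and 2032 lower with size factors, and 2199 and 1641 with library totals alone. Most changes were small: the median size among these genes was 0.61 on the log2 scale, or 1.53-fold, while 516 genes rose and 412 fell at least 2-fold, and 35 rose and 51 fell at least 8-fold. Under this scaling, abundant genes fell more often than they rose. In bands of abundance set after the data were seen, among the 100 genes with the highest mean CPM, 15 were higher and 19 lower, and among the next 900, 103 were higher and 206 lower. Among the 11869 least abundant genes the balance was the other way, with 1285 higher and 868 lower. Cyclic loess scaling, which evens out any trend with abundance by its construction, gave 28 higher and 19 lower, 178 and 178, and 1049 and 1092 in these bands. The 100 most abundant split into 15 higher and 33 lower without Cu-replete replicate 1, 10 and 13 without replicate 2, and 19 and 18 without replicate 3, and the next 900 into 96 and 282, 83 and 143, and 124 and 194. The gene with the highest mean CPM over all 9 libraries took 1.21% ± 0.133 (SD, n = 3) of the counts in Cu-replete cultures. Its share was 1.18% ± 0.050 in Cu-transient and 0.722% ± 0.0335 in Cu-limited cultures.

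Of the genes selected by the naming rule, c3733_g1 rose most in Cu-limited cells, from 3.36 ± 0.882 CPM to 91.7 ± 6.32 CPM (SD, n = 3), a log2 fold change of 4.75 ± 0.14 (SE; edgeR adjusted p = 1.04e-08). The length implied by the tables for this gene was 251 nt. The next, c4507_g1, rose from 6.78 ± 2.56 to 130.2 ± 9.05 CPM, a log2 fold change of 4.23 ± 0.22 (SE; edgeR adjusted p = 3.61e-07). The largest fall under the naming rule was that of c24995_g1, from 54.3 ± 4.96 to 0.207 ± 0.134 CPM. Its log2 fold change was -8.16 ± 0.23 (SE; edgeR adjusted p = 1.04e-08), and the 3 Cu-limited libraries together held 11 counts against 2787 in the Cu-replete libraries. The last, c20828_g1, fell from 41.2 ± 24.95 to 3.21 ± 3.36 CPM, a log2 fold change of -3.66 ± 1.11 (SE; edgeR adjusted p = 0.0412). Its level in the Cu-transient libraries ranged from 4.40 to 72.7 CPM, and its call was lost in 12 of 24 other settings, among them the replicate block (adjusted p = 0.0565) and leaving out Cu-replete replicate 3 (adjusted p = 0.218). The libraries of the groups compared did not overlap for 38.2% of all genes tested, where chance gives 10% on average. Genes are not independent of each other, so chance can also give a share far from 10%. This share was not computed for other splits of the libraries.

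A group of genes was close to silent in the Cu-limited line alone. By a definition chosen after the data were seen, 22 genes were at least 10-fold lower, and 16 at least 10-fold higher, in Cu-limited cultures than in each of the other groups, with at least 1 CPM in the higher group or groups. No gene met the same definition for the Cu-replete or the Cu-transient cultures, in either direction. All 22 and all 16 passed the edgeR test both against Cu-replete and against Cu-transient cultures. The sets were picked from the same values, so this adds little. Of the 22, 7 had no count in any Cu-limited library and 8 had 1 to 3 counts. One of the latter, c3684_g1, also picked after its values were seen, had 1303 counts in the Cu-replete libraries and 1 in the Cu-limited libraries, a ratio of 1526 after scaling (95% counting interval 273 to 60327). A further gene, c24100_g1, had 401 counts against 0. The lower limit of its 95% counting interval was 127-fold, and a floor of 3 counts over the group gives 156.6-fold. These intervals and floors cover counting error only. In Cu-transient cultures the median log2 fold change from Cu-replete was -0.11 over the 22 genes (95% bootstrap interval -0.30 to 0.01) and 0.41 over the 16 (-0.01 to 1.04), sets whose definition itself asks for a distance between Cu-transient and Cu-limited levels. One gene of each set passed the test in that comparison: c14878_g1, which fell by 0.97 on the log2 scale, and c3733_g1, which rose by 1.14. The bootstraps resampled genes, which all share the same libraries. Their intervals therefore leave out the spread between libraries.

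The second comparison asked what differed about 4 generations after Cu-replete cells were moved to medium with 1.4 nM copper. No matched transfer into medium with 21.4 nM copper is among the samples. Effects of the transfer and of low copper therefore cannot be told apart. Expression of 1388 genes differed between Cu-transient and Cu-replete cultures, 8.23% of those tested, with 803 higher and 585 lower. The median size was 0.50 on the log2 scale, or 1.41-fold. At least 2-fold changes were mostly rises, 95 against 21 falls, and 4 genes rose and 2 fell at least 8-fold. Of the 100 most abundant genes, 17 were higher, 1 was lower and 82 did not pass, and among the next 900, 79 were higher and 31 lower. When libraries were scaled by their totals alone, the split of all calls turned to 564 higher and 1098 lower, so the balance of rises and falls over all genes rests on the scaling. The 100 most abundant kept more rises than falls, with 21 and 3 under that scaling and 16 and 6 under cyclic loess, while the next 900 split into 81 and 82, and 106 and 80. Without Cu-replete replicates 1, 2 and 3 in turn, the 100 most abundant split into 16 and 2, 6 and 0, and 26 and 1, and the next 900 into 84 and 60, 35 and 10, and 126 and 26. The 100 genes with the highest mean CPM over all 9 libraries, taken as 1 fixed set, held 18.1% ± 0.775 of the counts in Cu-transient cultures. In Cu-replete cultures they held 16.6% ± 0.855 (SD, n = 3).

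The gene with the largest rise under the naming rule, c16730_g1, went from 5.92 ± 5.66 to 45.01 ± 14.3 CPM (SD, n = 3), a log2 fold change of 2.99 ± 0.68 (SE; edgeR adjusted p = 0.0249). This call was lost in 7 of 24 other settings. The second, c15231_g1, rose from 6.04 ± 0.539 to 32.5 ± 2.23 CPM, a log2 fold change of 2.43 ± 0.11 (SE; edgeR adjusted p = 3.46e-06), and stood at 17.9 ± 1.07 CPM in Cu-limited cultures, between the other groups. The largest fall under the naming rule, which leaves out genes of low mean level, was that of c14312_g1. It went from 381 ± 24.6 to 175 ± 3.04 CPM (log2 fold change -1.12 ± 0.08, edgeR adjusted p = 1.14e-04), with 136 ± 9.31 CPM in Cu-limited cultures. It was followed by c5679_g1, from 20.9 ± 1.84 to 10.3 ± 1.64 CPM (log2 fold change -1.02 ± 0.13, edgeR adjusted p = 0.00151). The libraries did not overlap for 26.7% of all genes tested, where chance gives 10% on average, with the same limit as in the first comparison. The number of calls depended on single libraries more than in the other comparisons: it was 483 without Cu-replete replicate 2, 491 without Cu-transient replicate 3, 848 without Cu-transient replicate 1, 916 without Cu-limited replicate 1 and 2518 without Cu-replete replicate 1, and 525 when only the 6 libraries compared were fitted.

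**Figure D2:**
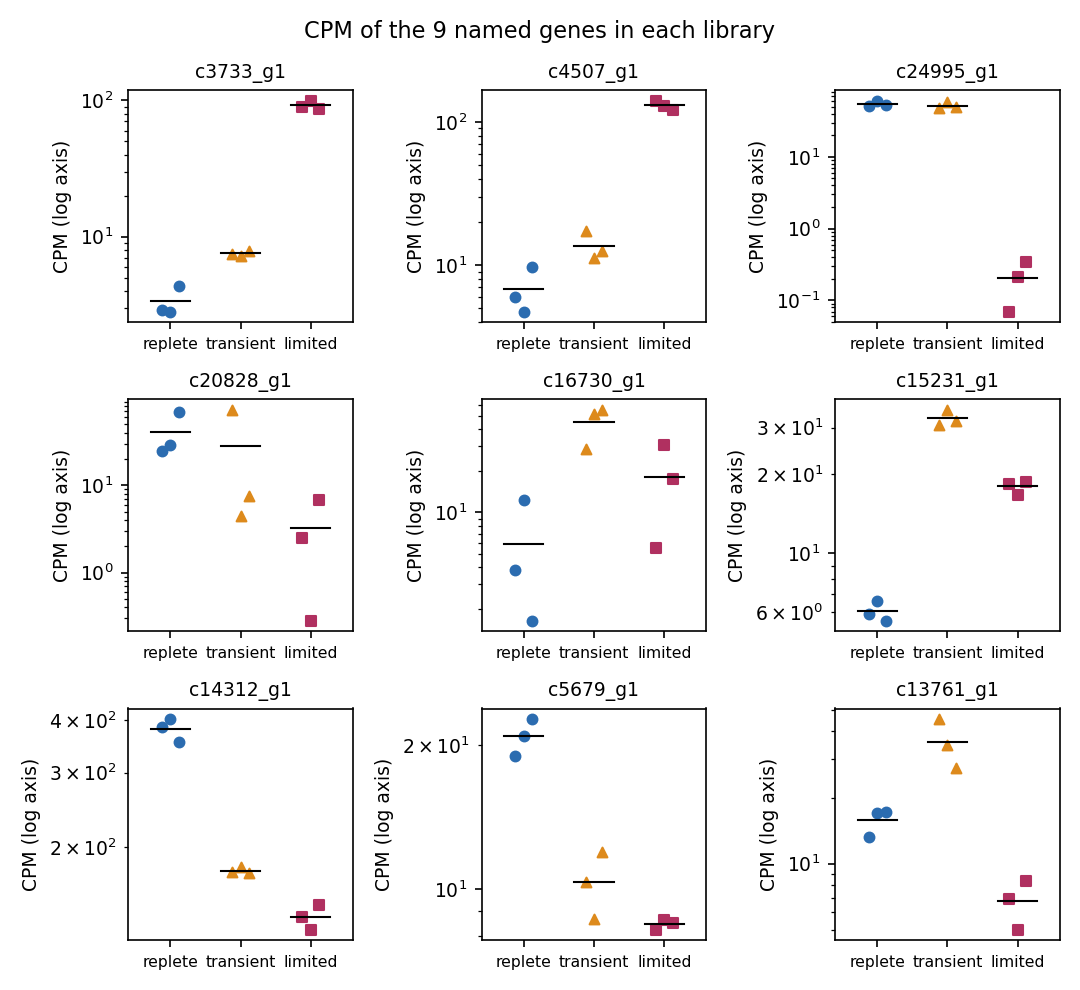
CPM, on a log axis, of the 9 genes that the naming rule selected, in each of 3 libraries per group; points are libraries and bars are group means. For c24995_g1 the 3 Cu-limited libraries lie at 0.0698 to 0.338 CPM and the other 6 at 48.4 to 59.98 CPM, whereas the Cu-transient libraries of c20828_g1 spread from 4.40 to 72.7 CPM.

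The third comparison set adapted Cu-limited cells against Cu-transient cells. These groups differ in the time spent at low copper, but also in line, in recent transfer and in copper level (1 against 1.4 nM). The Cu-limited line also grew at about 50% of the maximum rate. Effects of these differences cannot be told apart. Expression of 3900 genes differed, 23.1% of those tested, with 1960 higher and 1940 lower in Cu-limited cells and a median size of 0.57 on the log2 scale, or 1.48-fold. At least 2-fold, 387 were higher and 396 lower. Of the 100 most abundant genes, 40 were lower, 7 higher and 53 did not pass, and of the next 900, 251 were lower, 85 higher and 564 did not pass. This lean to lower expression was kept with size factors, at 41 lower and 7 higher, and 263 and 84. Library totals alone gave 39 and 10, and 220 and 143. Without Cu-replete replicates 1, 2 and 3 in turn, the 100 most abundant split into 47 and 7, 31 and 7, and 54 and 8. The lean was absent with cyclic loess scaling, which evens out any trend with abundance by its construction. That scaling gave 18 lower and 20 higher, and 177 and 174. The naming rule again gave c3733_g1 (log2 fold change 3.60 ± 0.13, edgeR adjusted p = 1.19e-07), c4507_g1 (3.26 ± 0.21, edgeR adjusted p = 2.38e-06) and c24995_g1 (-8.09 ± 0.23, edgeR adjusted p = 1.56e-08). It added c13761_g1, at 35.8 ± 9.19 CPM in Cu-transient, 15.8 ± 2.29 CPM in Cu-replete and 6.77 ± 1.67 CPM in Cu-limited cultures (SD, n = 3), with a log2 fold change of -2.39 ± 0.22 (SE; edgeR adjusted p = 2.77e-05). With libraries scaled by their totals alone, the split of calls was 3184 higher and 1422 lower. The count of calls was 2456 without Cu-limited replicate 1 and 2429 without Cu-limited replicate 3. The libraries did not overlap for 44.7% of all genes tested, where chance gives 10% on average, with the same limit as in the first comparison.

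Setting the 3 tests side by side sorted the genes into classes chosen after the data were seen. The classes compare an adapted line with a recent transfer of the other line, and are not time points of one response. The largest class, 2039 genes, differed in Cu-limited cells from both other groups and did not pass the test in Cu-transient against Cu-replete cells. In it, 1120 genes were higher, with a median log2 fold change against Cu-replete of 0.66 in Cu-limited and 0.01 in Cu-transient cells, and 919 were lower, with medians of -0.71 and -0.03. A class of 427 genes showed the reverse, differing in Cu-transient cells from both other groups but not passing the test in Cu-limited against Cu-replete cells. Of these, 294 were higher in Cu-transient cells, with a median log2 fold change of 0.53 there and 0.02 in Cu-limited cells, and 133 were lower, with medians of -0.37 and -0.01. The medians near 0 follow from how the classes are defined. The class of Cu-transient cells held 708 genes without Cu-replete replicate 1 and 118 without Cu-transient replicate 3.

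Both low-copper groups differed from Cu-replete cells in the same direction for 639 genes, 313 higher and 326 lower. They made up 17.0% of the genes called in Cu-limited cells and 46.04% of those called in Cu-transient cells. The shared count was 1148 without Cu-replete replicate 1, 253 without Cu-replete replicate 2, 308 without Cu-transient replicate 3 and 413 without Cu-limited replicate 1. In 174 of them the change was larger in Cu-limited cells by the direct test: 95 genes rose by a median of 1.46 in Cu-limited and 0.64 in Cu-transient cells on the log2 scale, and 79 had medians of -1.06 and -0.48. In 26 the change was larger in Cu-transient cells, and for 439 the direct test found no difference between the low-copper groups. Independent lists of these sizes would share 91.7 higher and 63.3 lower genes, a value that leaves out the shared controls. The 20 simulations of unchanged groups against the same controls shared 0, but made at most 1 call per comparison, so they could hardly have shared any. Across genes, which are not independent replicates, the fold changes of both comparisons correlated at 0.37 against 0.49 in the simulations, 63.7% against 66.6% had the same sign, and their covariance was 0.0891 against 0.0316, a difference of 0.0575. The simulations gave all groups the same dispersion per gene, with independent noise. In the data the Cu-replete libraries varied most, with a median SD of log2 CPM of 0.137 against 0.078 in Cu-limited and 0.108 in Cu-transient libraries. The simulated covariance may therefore be too low, and the difference does not measure a response beyond the shared controls. The 3 control libraries cannot give each comparison 2 of its own, and no split of them was run for this count. Part of the excess of shared calls may therefore come from the controls that both comparisons share.

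A smaller class of 66 genes changed in opposite directions. Independent lists would give 154, but the controls that both comparisons share push fold changes towards the same sign, so that number is not what chance gives here. In 52 of them expression was lower in Cu-limited and higher in Cu-transient cells than in Cu-replete cells, with medians of -0.41 and 0.42 on the log2 scale, and in 14 it was the reverse, with medians of 0.37 and -0.36. Changes were at least 2-fold in both directions for 2 of the 66, one being c13761_g1, with log2 fold changes of -1.21 in Cu-limited and 1.18 in Cu-transient cells. A further 1168 genes differed between the low-copper groups while neither differed from Cu-replete cells by the test.

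**Figure D3:**
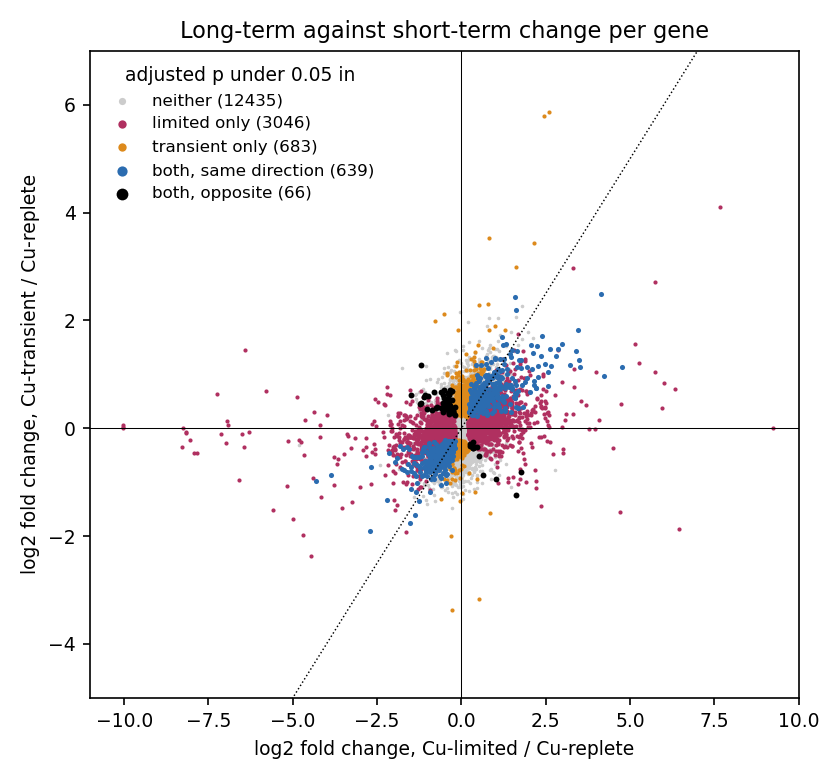
Log2 fold change of each of 16869 genes in Cu-transient against Cu-replete cells (vertical axis) and in Cu-limited against Cu-replete cells (horizontal axis), coloured by which comparison passed adjusted p 0.05; the dotted line marks equal change. Genes called in both comparisons number 639 in the same direction and 66 in opposite directions, and the points near -8 to -10 on the horizontal axis are genes nearly without counts in the Cu-limited libraries.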

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

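The tests of a graded response, of gene length, of background reads (in place of a planned ratio of median differences between bands, undefined because the lowest median was 0) and of genes whose partners took too few reads or are lacking were chosen only after the result was seen.

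A difference between groups drew attention to 66 genes that moved in opposite directions under long-term and short-term low copper. All also differed between the low-copper groups by the direct test (edgeR, adjusted p 0.05), which nearly follows from opposite calls against the same controls and adds little. The count was 21 without Cu-replete replicate 2, 28 without Cu-transient replicate 3, 31, 40 and 36 without Cu-limited replicates 1, 2 and 3, and 42 without Cu-transient replicate 1.

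For the 22 genes at least 10-fold lower in Cu-limited cells than in both other groups, a graded copper response already under way in the Cu-transient cells stays open: the median log2 fold change there was -0.11 over the 22 genes, but their definition leaves out genes already far down in Cu-transient cells, and over the 36 genes at least 10-fold lower than in Cu-replete cells, whatever their Cu-transient level, it was -0.34 (95% bootstrap interval -0.53 to -0.13), a value that selection on the shared controls biases downwards. With such genes picked without 1 Cu-replete library and measured against that library alone, the medians were -0.38 to -0.28, and each 95% bootstrap interval reached below the -0.5 set as a mark of such a response. These bootstraps resampled genes, so the intervals leave out the spread between libraries. Loss of reads to another gene of the same assembly component cannot apply to the 14 genes with no such partner, which follows from the definition alone. It is argued against, but not excluded, for 3 of the other 8. Their partners gained less than the gene lost even between their highest Cu-limited and lowest Cu-replete library. A fall in the partners' own expression could hide a gain of reads. Loss of reads to a partner stays fully open for 5, and 3 of the 8 had a partner that rose by the test. Loss of reads to similar genes of other components was not tested for any of the 22. RNA of another organism or strain carried in the Cu-replete line stays open: deviations of the 22 genes across the 6 Cu-replete and Cu-transient libraries correlated at -0.034 on average, under the 0.17 that marks the top 5% of 1000 random sets, but the second condition set for excluding it, that their fold changes differ by more than error, was met (p = 2.73e-06) only through c14878_g1 (p = 0.175 without it), so that condition was wrongly drawn, a judgement made after the result was seen. Also open, as a hypothesis, is a difference between lines: the Cu-transient cells descend from the Cu-replete line, so loss or silencing of genes during more than 500 generations of separate culture may give the same pattern as a slow copper response, and the design confounds them.

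Cu-replete replicates 1 and 3 differed in an abundance-dependent way: the rank correlation of their log2 ratio with abundance, across genes, was -0.36, with medians of 0.39 in the band of lowest abundance and -0.17 in the highest, while it was -0.33 for replicates 1 and 2, -0.25 for 2 and 3, and at most 0.19 in size in the other groups. Sequencing depth is argued against as the whole cause, since the correlation was still -0.36 after thinning both libraries to 1 total, and gene length is argued against by a rank correlation of -0.063. A constant level of background reads in replicate 1 is argued against because the mean FPKM difference was 3.39 times as large in genes of 2 to 5 FPKM as in genes of 0.5 to 1 FPKM (95% interval from a bootstrap over genes 3.04 to 3.81). What separates the libraries stays open, and no biological explanation was tested, because both carry the same group label. Leaving out replicate 1, 2 or 3 gave 2518, 483 or 1397 calls between Cu-transient and Cu-replete cells and cyclic loess scaling 1688, against 1388, and whether the trend accounts for any of these was not tested.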

How the results depend on the processing

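Cyclic loess, thinning, the response classes and the 10-fold sets with all their settings were chosen after the data were seen. Counts for the 3 comparisons stayed within 1.5 times the reported ones with other scalings, other filters on low counts, DESeq2, limma-voom, limma on FPKM, cyclic loess and thinning to the smallest total; for genes differing among the groups, scalings by size factors or totals, the filters, the block and leaving out libraries were run. At an adjusted p of 0.01 calls fell to 2162 (Cu-limited against Cu-replete), 357 (Cu-transient against Cu-replete), 2041 (Cu-limited against Cu-transient) and 202 (shared), as a stricter threshold must give. Tested against a 2-fold change, 278, 2 and 185 genes passed, against 928, 116 and 783 called with a fitted change of at least 2-fold, as this test by construction asks that the change exceed 2-fold by more than its error. Fitting only the 6 libraries compared gave 525 calls for Cu-transient against Cu-replete, 3167 for Cu-limited against Cu-replete and 5144 for Cu-limited against Cu-transient. The median SD of log2 CPM within a group was 0.137 in Cu-replete, 0.108 in Cu-transient and 0.078 in Cu-limited libraries. These medians cover genes with a mean log2 CPM of at least 3. The fit of all 9 libraries gives the groups 1 shared spread, and whether this accounts for the shifts was not tested. DESeq2 gave 106 genes in opposite directions; the cause was not tested. At 5-fold the Cu-limited sets held 34 lower and 41 higher genes, and at 20-fold 8 higher, as the limit itself implies.

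Leaving out 1 library gave 2586 to 4405 calls for Cu-limited against Cu-replete, 483 to 2518 for Cu-transient against Cu-replete, 2429 to 5035 for Cu-limited against Cu-transient, and 3338 to 6531 for any difference (3338 without Cu-limited replicate 1, 3371 without Cu-limited replicate 3). Shared calls were 253 to 1148 (1148 and 253 without Cu-replete replicates 1 and 2, 413 without Cu-limited replicate 1, 308 without Cu-transient replicate 3). Genes differing in Cu-limited cells alone were 1360 to 2435. Genes differing in Cu-transient cells alone were 118 to 708 (167 without Cu-replete replicate 2, 200 and 199 without Cu-limited replicates 1 and 3, 241 without Cu-transient replicate 1). Genes in opposite directions were 21 to 71, and the 10-fold sets 19 to 28 lower and 17 to 20 higher. Of 12 gene calls, c20828_g1 and c16730_g1 were lost in 12 and 7 of 24 settings, c14312_g1 and c5679_g1 in 1 (the 2-fold test), and none turned direction.

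With the replicate block, calls were 3325, 1021 and 3448 in the 3 comparisons, 4368 for any difference, 497 shared, 1822 and 301 in the classes of Cu-limited and Cu-transient cells alone, and 46 in opposite directions; among named genes it ended the call of c20828_g1. The numbers showed no clear pairing: deviations of 9 same-numbered pairs correlated at -0.30 to 0.22, and 1 of 9 libraries correlated best with its own number. With 3 libraries per group this check cannot show that pairing is absent. Camera, fry and the estimated correlation were not run, because no list could be matched to IDs.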

Other observations

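The test of genes within one assembly component was planned before its result was seen. All genes singled out by ID in this section were chosen after their values were seen.

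Some genes had their most extreme level in Cu-transient cells. Expression of c12410_g1 was 9.87 ± 1.48 CPM in Cu-replete, 1.10 ± 0.148 CPM in Cu-transient and 14.0 ± 4.31 CPM in Cu-limited cultures (SD, n = 3; log2 fold change of Cu-transient against Cu-replete -3.16 ± 0.27 SE, edgeR adjusted p = 2.69e-04). Its level in Cu-limited cells did not pass the test against Cu-replete (edgeR adjusted p = 0.108). In the other direction, c2367_g1 rose from 0.706 ± 0.370 CPM in Cu-replete to 39.3 ± 39.0 CPM in Cu-transient cultures (log2 fold change 5.79 ± 0.92 SE, edgeR adjusted p = 0.00465), with a spread between libraries about as large as its mean. It stood at 4.04 ± 3.42 CPM in Cu-limited cultures, a log2 fold change of 2.44 against Cu-replete that did not pass the test (edgeR adjusted p = 0.121).

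Among very abundant genes, c6401_g2 rose from 1347 ± 167 CPM in Cu-replete to 2347 ± 552 CPM in Cu-transient and 4702 ± 142 CPM in Cu-limited cultures, with log2 fold changes against Cu-replete of 0.80 (edgeR adjusted p = 0.0186) and 1.80 (edgeR adjusted p = 2.85e-05). The gene c18186_g1 was at 12086 ± 2076 CPM in Cu-replete, 12213 ± 822 CPM in Cu-transient and 7010 ± 380 CPM in Cu-limited cultures, where it fell by 0.79 on the log2 scale (edgeR adjusted p = 0.00381).

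Genes of one assembly component changed together. Of 290 pairs of genes called between Cu-limited and Cu-replete cells that share a component, 81.4% changed in the same direction, against a median of 50% and a highest value of 60.7% in 1000 permutations of the directions (permutation p = 0.001, the smallest they can give). Pieces of one transcript counted as separate genes, reads shared between similar genes and copies regulated together may each give this, and no value here separates them. Counts of changed genes may therefore exceed the number of separate loci that changed.

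Other groupings of the 9 libraries gave fewer genes that differ among groups: of 100 splits, 1 (the real one) gave as many as 5057, and the highest other gave 3359. Random assignment of these libraries to groups is thus an unlikely source of this count. The splits cannot exclude chance differences between cultures, because the replicates of a group may be technical. The 4 splits that kept the Cu-limited libraries together gave 1966 to 3359 calls and no other split gave more than 112, which shows how far the contrast of Cu-limited with all other libraries shapes the data. For each pair of groups, 1 of 10 splits gave as many calls, and 10 splits are too few for a share under 0.05. The real and highest other counts were 3751 and 4 for Cu-limited against Cu-replete, 1388 and 0 for Cu-transient against Cu-replete, and 3900 and 2 for Cu-limited against Cu-transient.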
